A study of Mus musculus with 4 samples.

How the data were processed

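Gene expression was measured in 4 samples of sorted mouse embryonic stem cells on 4 microarrays, 2 samples of Emerald-positive cells and 2 of Emerald-negative cells. Per the labels, each sample's RNA was labelled with Cy3 and hybridised together with a Cy5-labelled reference pool of RNA from 11 mouse cell lines, with the same dye orientation on every array. Groups and replicate numbers were taken from the sample titles. The array was the NIA mouse oligonucleotide design made by Agilent, with 42006 probes of 60 bases on 42034 spots, 314 negative-control spots and 1942 positive-control spots.

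The deposited scanner tables hold spot intensity on a linear scale for each channel, with the local background, and also processed intensities that the software had background-subtracted and dye-normalized, per the file headers. The file headers name Feature Extraction version 7.5.1, while the series' design text names version 9.5.1.1. The scanner tables also hold a log10 ratio of Cy5 over Cy3, per the file headers. The authors' deposited value table is on a log10 scale, and its steps are not given in the sources used here. Set against the scanner values, its columns correlated with the log2 Cy3 processed signal (r from 0.992 to 0.994 across probes), and each array's deviation from the 4-array mean followed that of the sample-over-reference ratio (r from 0.996 to 0.999). Its column medians were 2.957 and 2.950 for Emerald-positive replicates 1 and 2, and 2.954 and 2.948 for the Emerald-negative replicates. Its direction between arrays was therefore taken as sample over reference, and its centring stays unknown.

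For the main analysis, mean signals were corrected against median local backgrounds with normexp (offset 50) and normalized within each array by loess, with control spots and outlier spots at weight 0. Ratios were turned to log2 of sample over reference. The 403 outlier spot values marked by the scanner software were left out, which left 400 probes without all 4 values, and spots of the same probe were averaged. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The test, its groups, the rule for named items and most alternatives were fixed before the data were examined.

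The planned filter kept probes well above background in Cy3 on both arrays of at least 1 group. The software's mark for this was set for 100% of probes and also for 100% of negative-control spots on every array, so this filter, its stricter form and the absence of a filter gave the same 42006 probes, with 0 removed. A filter against the negative-control spots was added after seeing the data. It required a net Cy3 signal above their mean plus 2.6 SD on both arrays of at least 1 group, and it removed 4790 probes.

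The files give no gene name for any probe (0 of 42006), and 0 matched the reference gene table of assembly GRCm38.p6. The planned gene lists, the planned level of the reporter's own gene family and the planned cell type markers were therefore not analysed here, and probes are reported by identifier and sequence. The planned rule named up to 12 genes with a symbol in each direction. In its place, the 2 probes with the largest rise and the 2 with the largest fall past the threshold, changed the same way on both days, were named.

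The descriptions give both samples of a replicate number the same day, and the scanner tables' 2 extraction days split the arrays in the same way. The replicate number therefore pairs the samples, and a fit with the replicate number as a block was run as an alternative. Deviations of paired samples from their group means correlated across probes (r = 0.475). Each array was on its own slide, 4 slides in all. No source used here says whether the days were separate cultures, so p-values measure the spread between these samples, which may be partly technical.

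Other alternatives covered background correction, loess, scaling between arrays, the sample channel without the reference, the authors' value table, an intensity trend in the prior variance, an unmoderated one-way test, a 2-fold minimum, and leaving out each array. Probes were linked by sequence with blastn 2.17.0 on the same strand, over at least 24 bases at 80% identity or more, and linked probes formed families. Of all probes, 2730 were linked to another, and 57 families held 5 or more probes (583 probes). Families were tested with camera of limma, at a preset correlation of 0.01 and with an estimated correlation. These family steps were added after seeing the data.

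The limma, sequence-link and camera steps were tested on simulated data. In 10 simulated sets of 42006 probes with 200 changed probes, 2 arrays against 2, limma recovered 47.3% of 2-fold, 90.4% of 4-fold and 97.4% of 8-fold changes, with 4.97% false calls. These simulated probes varied independently and without a day effect, so the shares may not hold for the measured arrays. For sequence links, 40 of 40 planted links among 540 sequences were found, with 0 false links. For camera, 5 of 57 families of the 42006-probe array were raised 2-fold in each of 10 sets. With independent probes, 50 of 50 raised families were found at the preset correlation (2 false calls) and 2 of 50 with the estimated one (0 false calls). With probes of a family correlated at 0.649, the median estimated correlation of the families past the preset test, the preset found 50 of 50 but also called 154 of 520 families that were not raised, and the estimated correlation found 0 of 50 with 0 false calls.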

Results

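Mouse embryonic stem cells of a 129/Sv clone carried Emerald, a green fluorescent protein, under the promoter of Zscan4c. The cells were sorted by fluorescence into Emerald-positive and Emerald-negative fractions, and the comparison asks how expression differs between cells with an active and an inactive reporter. Each fraction was measured on 2 arrays, 1 for each of 2 days. Median net Cy3 signals were 241 and 122 in Emerald-positive replicates 1 and 2, and 217 and 136 in Emerald-negative replicates 1 and 2. Against the negative-control spots, 89.4%, 93.6%, 86.6% and 79.3% of probes stood above the mean plus 2.6 SD on these arrays, in the same order. The number of arrays limits the precision of every value.

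Without the replicate block, few probes were called different between the fractions, and nearly all of these calls were higher in Emerald-positive cells. This count is no measure of how many probes differ, because the same test recovered 47.3% of simulated 2-fold changes. Of 42006 probes, 92 rose and 4 fell in Emerald-positive cells. Of the 92 rises, 89 exceeded 2-fold, 61 exceeded 4-fold, 43 exceeded 8-fold and 23 exceeded 16-fold. The median of the 92 rises was 2.89 on the log2 scale, or 7.40-fold, over a range of 0.95 to 5.53. These sizes partly follow from the threshold, because the test recovered 97.4% of simulated 8-fold but 47.3% of simulated 2-fold changes. The median of the same probes was 1.92 without background correction and 3.42 with the sample channel alone. The 4 falls lay between -1.16 and -1.89 on the log2 scale. The count of lower probes was 1 with normexp offset 10 or without background correction, and 0 with the sample channel alone. The 92 and 4 calls were made with limma at an adjusted p under 0.05, and 3038 probes had an unadjusted p under 0.05, 1570 of them higher and 1468 lower. The adjusted p of 3 of the higher probes and 1 of the lower probes rounds to 0.05, so these calls lie at the threshold. With the replicate number as a block, 309 probes were higher and 49 lower, and these included all 92 and all 4 of the unblocked calls. The count of higher probes was 47 without background correction, 17 without Emerald-negative replicate 1, 18 without Emerald-negative replicate 2 and 61 without Emerald-positive replicate 2, and an unmoderated one-way test left 0 probes in either direction after adjustment, with 2223 at an unadjusted p under 0.05.

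Probe Z00058166-1 was 1 of the 2 with the largest rises, with the sequence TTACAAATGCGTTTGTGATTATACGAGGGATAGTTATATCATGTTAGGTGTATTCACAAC. Its log2 level against the reference pool was 5.97 ± 0.15 (SD, n = 2) in Emerald-positive cells and 0.44 ± 0.67 (SD, n = 2) in Emerald-negative cells. The difference was 5.53 (SE 0.33), or 46.1-fold, with a limma adjusted p of 0.0188, and was 4.94 and 6.11 on the separate days. Without Emerald-positive replicate 1 its adjusted p was 0.0771, and without Emerald-positive replicate 2 it was 0.109. With the sample channel alone the difference was 7.20.

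Probe Z00034921-1, with the sequence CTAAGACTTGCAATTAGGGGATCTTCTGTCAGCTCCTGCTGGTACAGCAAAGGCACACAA, rose by 5.49 (SE 0.15) on the log2 scale, or 45.1-fold, with a limma adjusted p of 0.00308. Its level was 5.29 ± 0.24 (SD, n = 2) in Emerald-positive cells and -0.21 ± 0.15 (SD, n = 2) in Emerald-negative cells. It stayed past the threshold without any single array, and its 2 days gave 5.22 and 5.77. With the sample channel alone the difference was 7.77. The order of the largest rises depended on the processing: this difference exceeded that of Z00058166-1 with normexp offset 10 (5.63 against 5.54), processed signals, the authors' value table and the sample channel alone, and without Emerald-positive replicate 1 or Emerald-negative replicate 2.

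The largest fall was at probe Z00010489-1, with the sequence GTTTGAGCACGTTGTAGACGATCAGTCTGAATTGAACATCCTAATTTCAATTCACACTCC. Its level was -0.05 ± 0.01 (SD, n = 2) in Emerald-positive cells and 1.84 ± 0.12 (SD, n = 2) in Emerald-negative cells, a difference of -1.89 (SE 0.09) with a limma adjusted p of 0.0105. Leaving out any 1 array ended the call, with adjusted p from 0.0595 to 0.0935, and with the sample channel alone the adjusted p was 0.122. Without background correction the difference was -0.89.

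Probe Z00063266-1, with the sequence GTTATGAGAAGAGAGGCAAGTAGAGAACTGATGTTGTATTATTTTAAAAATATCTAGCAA, differed by -1.40 (SE 0.12), with levels of 0.07 ± 0.19 (SD, n = 2) in Emerald-positive and 1.47 ± 0.03 (SD, n = 2) in Emerald-negative cells. Its limma adjusted p was 0.0305 with the replicate block and rounds to 0.05 without it. In 14 of the alternatives its adjusted p was above the threshold, up to 0.776, and without background correction the difference was -0.54.

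In log2 ratio to the reference pool, the 92 higher probes stood far above the centre of all probes in Emerald-positive cells and close to it in Emerald-negative cells. Their median log2 ratio was 3.04 and 3.21 in Emerald-positive replicates 1 and 2, and -0.01 and -0.02 in Emerald-negative replicates 1 and 2. Over all probes, which loess centres on each array, the medians were -0.013 and -0.013 on the Emerald-positive arrays, and -0.0095 and -0.011 on the Emerald-negative arrays. A ratio near this centre is therefore not by itself a level equal to that of the pool. More than 2-fold above the reference were 84 and 83 of the 92 higher probes on the Emerald-positive arrays, and 7 and 5 on the Emerald-negative arrays. Their median net Cy3 signal was 1521 and 1629 in Emerald-positive cells, and 149 and 94.3 in Emerald-negative cells. All 92 were above the negative-control level on both Emerald-positive arrays. On the Emerald-negative arrays, 69 were above it on both, 10 on 1 and 13 on neither, which limits how well those folds were measured.

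**Figure D1:**
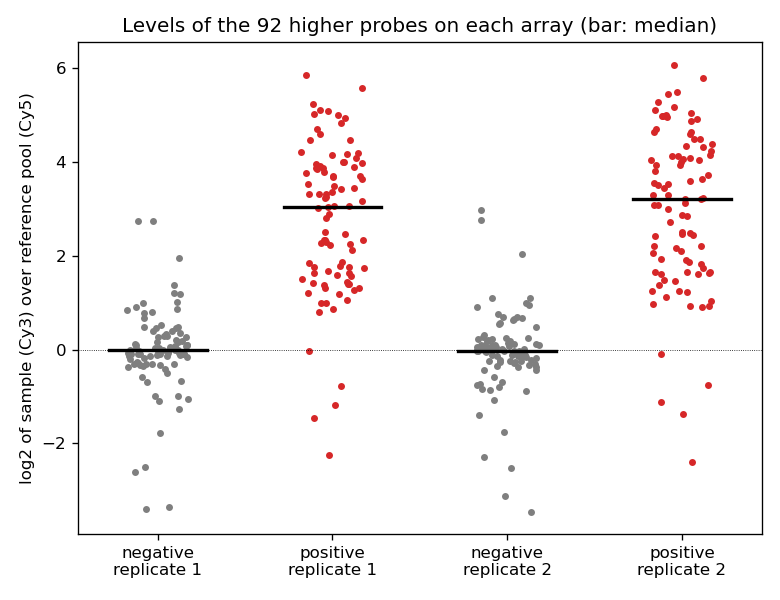
Log2 ratio of sample (Cy3) over reference pool (Cy5) of the 92 higher probes on each array, 1 point per probe, with the median as a bar. The medians are 3.04 and 3.21 on the Emerald-positive arrays and -0.01 and -0.02 on the Emerald-negative arrays.

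The difference between the sorted fractions was compared between the 2 days, which share no array. At least 2-fold higher were 290 probes on the replicate 1 day and 366 on the replicate 2 day, with 204 on both, where independent lists would share 2.55. At least 2-fold lower were 48 and 68 probes, with 9 on both and 0.0785 in independent lists. Without background correction, 109 probes were at least 2-fold higher and 2 lower on both days, and 16 were lower on both with normexp offset 10 or the sample channel alone. In the main analysis, no probe moved 2-fold in opposite directions (0 probes). Probes are not independent, so 2.55 and 0.0785 are no chance levels for them. Across all probes, which are not independent replicates, Pearson's r between the days was 0.65 and Spearman's rho was 0.273. Without the called probes, r was 0.508 and rho 0.268. With the sample channel alone, r was 0.232 and rho was -0.0495.

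**Figure D2:**
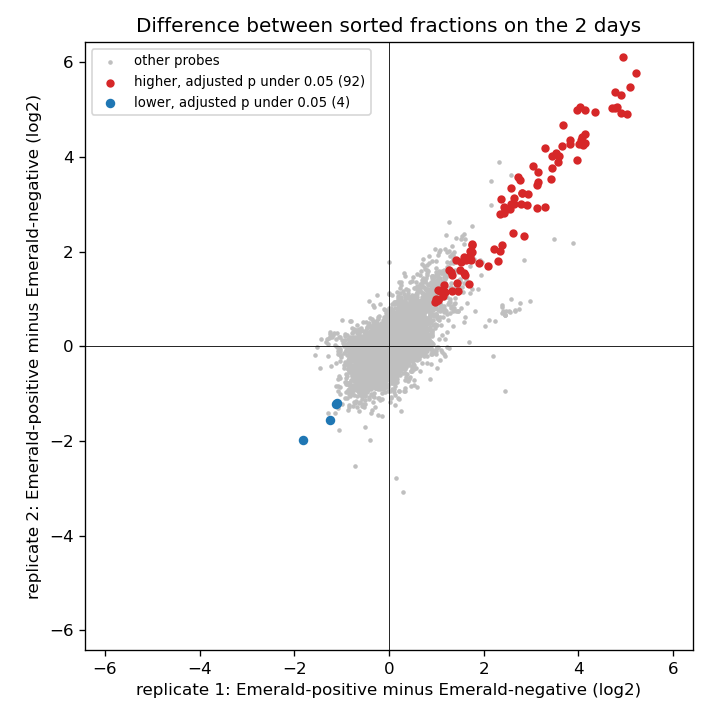
Emerald-positive minus Emerald-negative difference (log2) of every probe on the replicate 1 day (horizontal) and the replicate 2 day (vertical). Red points are the 92 probes higher and blue points the 4 probes lower at an adjusted p under 0.05, and grey points are all others; Pearson's r across probes was 0.65.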

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

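The outlier-spot and negative-control alternatives and the sequence family settings were chosen after seeing the data, and the rest were planned. With the replicate block, 309 probes were higher and 49 lower, against 92 and 4 without it, and the block changed none of the calls of the 4 named probes. The count of higher probes stayed within 1.5 times of 92 with normexp offset 10, processed signals, median centring, scaling between arrays, the sample channel alone, the authors' value table, outlier spots kept, the negative-control filter, the intensity trend and the 2-fold minimum. It was 47 without background correction. Leaving out 1 array gave 17 to 92 higher and 0 to 1 lower probes, with the lone array assumed to vary like the other group. The unmoderated one-way test gave 1122 higher and 1101 lower probes at its unadjusted threshold, and 0 and 0 after adjustment. The count of lower probes was 1 with normexp offset 10, processed signals, no background correction or the authors' value table, 2 with median centring, outlier spots kept or the negative-control filter, and 0 with the sample channel alone. Pearson's r between the days was 0.547 with normexp offset 10, 0.574 with processed signals, 0.748 without background correction, 0.609 with median centring, 0.232 with the sample channel alone, 0.576 in the authors' value table, 0.596 with outlier spots kept and 0.679 with the negative-control filter. Spearman's rho in the first 6 of these was 0.246, 0.25, 0.305, 0.218, -0.0495 and 0.249. All 4 named probes kept their direction in every alternative run. Z00058166-1, Z00034921-1, Z00010489-1 and Z00063266-1 passed the threshold in 15, 17, 12 and 4 alternatives and missed it in 3, 1, 6 and 14. The passes of every named probe include the stricter planned filter and the absence of a filter, which repeat the main fit. For Z00063266-1 the limma adjusted p was clearly past the threshold in 2 settings only, the replicate block (0.0305) and the intensity trend (0.0426). Probes at least 2-fold lower on both days numbered 15 with processed signals and 14 in the authors' value table, against 9. The 19-probe family with the largest shift in the main analysis had a median of -0.0158 with the sample channel alone. Apart from fewer arrays or probes tested, the cause was not tested. Leaving out an array was not possible for the agreement of the days, which needs all 4. Planned settings for gene lists, markers and the reporter's gene family were not run, because the files give no gene names. Signals near the negative-control level limit dim probes.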

Other observations

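The share of higher calls across scalings was tested as predicted before its result was seen, and all other tests in this part were chosen after the results were seen.

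Some of the higher probes shared sequence. Of the 92, 15 were linked on the same strand to another of them, in 7 groups of at most 3 probes. In 10000 random sets matched on mean intensity, 0.0287 probes were linked on average and 3 at most (one-sided permutation p = 0.0001, the smallest these draws can give). The draws treat probes as independent. Probes that share sequence may measure the same transcripts and so be called together, so this excess is no count of separate transcripts that rose. In a pair chosen after its values were seen, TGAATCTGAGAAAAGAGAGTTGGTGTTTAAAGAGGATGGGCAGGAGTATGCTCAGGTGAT rose by 2.82 (SE 0.12) and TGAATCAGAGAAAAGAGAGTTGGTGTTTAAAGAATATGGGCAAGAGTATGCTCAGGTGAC by 3.60 (SE 0.11) on the log2 scale, with limma adjusted p of 0.00723 and 0.00408.

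Beyond the single-probe calls, 7 families of 5 or more probes had a median difference of at least 2-fold. Each had a camera adjusted p of 0.575 with the estimated correlation, so none passed. That test found 2 of 50 raised families with independent simulated probes and 0 of 50 with correlated ones, so it cannot show absence of a shift. At the preset correlation all 7 passed (camera adjusted p from 4.9e-18 to 2.0e-06), but the preset also called 154 of 520 correlated simulated families that were not raised. Each of the 7 fell below 2-fold in at least 1 alternative, with lowest medians from -0.0158 to 0.92 on the log2 scale. A 7-probe family with the most linked sequence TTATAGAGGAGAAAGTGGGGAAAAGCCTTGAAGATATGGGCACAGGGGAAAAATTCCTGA had a median difference of 1.07. A 5-probe family with the most linked sequence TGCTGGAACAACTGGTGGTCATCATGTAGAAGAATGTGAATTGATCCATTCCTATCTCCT also had a median of 1.07. With limma and the replicate block, 7 of 7 and 5 of 5 of their probes were called, against 0 and 0 without it. Without the block, the estimated correlations within these families were 0.992 and 0.945. Linked probes share sequence, so the calls of each family are not taken as independent. Families that do not overlap in sequence may still measure the same transcript. Whether these families, or others of the 7, measure separate transcripts was not tested, so they are not counted as separate shifts. With the block, the camera adjusted p with the estimated correlation was 0.881 for both the 7-probe and the 5-probe family. With groups and block both fitted, too few arrays are left to estimate a correlation within a family. This value therefore says nothing for or against the calls in these families. In the rest of the 7 families, the block called 0 of 19, 0 of 6, 0 of 5, 2 of 6 and 3 of 5 probes higher. Among families with a median under 2-fold, the block called 11 probes higher in a 24-probe family (median 0.92, 1 called without the block). It also called 2 in a 5-probe family (median 0.63) and 2 in a 99-probe family (median 0.41).

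More probes were called higher than lower in Emerald-positive cells, also with the replicate block (86.3% of calls). The choice of scaling as the cause was argued against by the lowest share of higher probes over the scaling alternatives, 95.9% of calls. All of these scalings left a small median difference over all probes, furthest at -0.0191 with the sample channel alone. A common centring of the arrays was therefore not tested as a cause. A difference in the reference channel was argued against by the higher probes' median Cy5 difference of 0.243 (log2), opposite to the direction needed. Repeated counting of a shared sequence was argued against by 0.913 sequence groups per higher probe. Probes of the same transcript that do not overlap are not linked, so repeated counting of transcripts was not tested. The 3 splits of 4 arrays are too few for a share under 0.05: only 1, the real one, called 96 or more probes (358 with the replicate block), and the highest other called 0 with limma, with 5127 probes at an unadjusted p under 0.05 for the split by day, which parts no pair, and 311 for the crossed split, which parts both (0 called and 420 unadjusted with the block). Both other splits hold the difference between fractions in their spread. Between the days, which share no array, 204 probes were at least 2-fold higher on both in the main analysis, and 0 moved 2-fold in opposite directions. Independent lists would share 2.55, but probes are not independent, so this is no chance level for them. What else than the reporter differed between the sorted fractions was not tested.

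In the main analysis, the largest median family shift was in a 19-probe family with the most linked sequence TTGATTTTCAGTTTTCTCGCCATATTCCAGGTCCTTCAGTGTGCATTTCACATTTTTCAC, whose log ratio was 1.61 higher in Emerald-positive cells, with 2.46 and 0.74 on the separate days, 0.947 without Emerald-negative replicate 1 and 2.3 without Emerald-negative replicate 2. It was not the largest without Emerald-negative replicate 1, where a 6-probe family had 1.55. More of the 19-probe family's sequences in the Emerald-positive sample was argued against by the Cy3 signal, whose median difference was 0.278 on the replicate 1 day and -0.285 on the replicate 2 day. The Cy5 reference signal had a median difference of -1.6 (log2), with median net signals of 11693 and 24416 on the Emerald-positive arrays against 50134 and 50415 on the Emerald-negative arrays. In Cy5, 4 and 3 of the 19 probes were saturated on the Emerald-negative arrays and 0 on the Emerald-positive arrays, which limits both differences, and 3 probes matching the opposite strand had a median log-ratio difference of 2.33. The shift may therefore come from the reference channel, although the same pool was labelled on every array per the labels, and neither what made that channel differ nor whether RNA or DNA gave these signals was tested.

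Whether families of related probes shifted as groups could not be settled. At the preset correlation, 18 of 57 families had a higher and 3 a lower test result in Emerald-positive cells, and 0 passed with an estimated correlation (lowest adjusted p 0.575). The median estimated correlation of these 21 families was 0.649, and in simulated families with that correlation the preset called 154 of 520 that were not raised, while the estimated one found 0 of 50 that were. A difference in the reference channel as the cause was argued against by the median Cy5 difference of 0.0248 (log2) over the 18 families, and in 17 of them, the 19-probe family being the exception, the Cy5 difference lay between -0.07 and 0.26 and above -0.25 of the log-ratio difference. The Cy3 signal was higher on both days in 88.9%, but in families picked for higher log ratios this does not settle whether there is a shift.

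Cy5 signals of the 92 higher probes were higher on the Emerald-positive array on both days for 59 probes (64.1%), against 20.4% of all probes. Their median Cy5 difference was 0.22 on the replicate 1 day and 0.37 on the replicate 2 day, on the log2 scale.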
